A study of Homo sapiens with 70 samples.

How the data were processed

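Messenger RNA of ejaculated spermatozoa was measured in 70 libraries from 67 participants. Of these, 53 had come for fertility assessment (the infertility group, 56 libraries, since 3 participants gave 2 samples each) and 14 were of proven fertility. Per the labels' protocols, sperm were washed, other cells of the ejaculate were lysed, polyadenylated RNA was selected with oligo-dT beads and libraries were made with the NEBNext Ultra II RNA kit. Per the series text, paired-end reads of 150 bp were sequenced.

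Raw counts per gene were deposited by the authors for each library, over 57500 Ensembl genes. Per the submitters' processing notes, bcl2fastq 2.20, Trimmomatic 0.36, STAR 2.5.2b and featureCounts from Subread 1.5.2 were used, with the GRCh38 genome build. Whether counting used strand is not given in the sources used here, so reads of a gene and of a gene that overlaps it on the opposite strand could not be separated. Of the 118 genes named by the rule below, 56 have a span, introns included, that overlaps the span of such a gene. Whether exons overlap was not examined, so fewer may be affected. Overlaps given below are of spans. No pair of libraries held identical counts. The authors also deposited log2 normalised values for 27809 genes and 67 participants. With 1 subtracted after the logarithm was undone, each column equalled the raw counts times a constant for 100.0% of genes, within a relative tolerance of 1e-06. For the 3 participants with 2 libraries this held for the summed counts, whereas the series text speaks of averaging. A sum and a mean differ only by the constant. Genes with deposited log2 values had at least 700 counts over all libraries, and the highest sum of any other gene was 699.

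Gene symbols and biotypes came from a table of gene names and from GENCODE 29, which covered 56898 of the genes. GC content was that of GENCODE transcripts, which 56845 genes had. Coordinates are those of the count files (GRCh38, counted from 1). Counts per gene were scaled to counts per 1000000 (CPM) by the participant's total. Totals ranged from 1339489 to 3190134 gene counts per library. At the smallest participant total, 10 CPM correspond to 13.4 counts, with a counting error of 27.3%. Reads carried no molecular identifiers, so this covers counting error only.

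The libraries of a participant with 2 were summed. Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, quasi-likelihood fit with robust empirical Bayes), with Benjamini-Hochberg adjustment at 0.05. All log2 fold changes are infertility over proven-fertile. The series text names a Wilcoxon signed-rank test. Since the groups hold different participants, a rank-sum test was run on the deposited log2 values, with a two-sided permutation p from 100000 resamples. Gene lists (21 in number, 716 of 718 entries matched) were tested with camera in limma 3.58.1, with the inter-gene correlation estimated from the data. They cover sperm chromatin packaging, flagellum fibrous sheath and outer dense fibres, axoneme and dynein arms, acrosome and egg binding or fusion, sperm ion channels and motility signalling, sperm glycolysis, meiosis and piRNA pathway, spermatid transcription and translation control, cytosolic ribosomal proteins, mitochondrially encoded proteins, nuclear respiratory chain, proteasome and ubiquitin, chaperones, antioxidant enzymes, DNA repair, interferon response, leukocyte markers, epithelial, prostate and seminal vesicle markers, epididymal epithelium markers, Sertoli, Leydig and peritubular markers, spermatogonia and early germ cell markers. Library properties were compared by permutation of group means (100000 resamples). Whole profiles, as 1 minus the Spearman correlation of log2 CPM with 0.5 added to each count, were compared by PERMANOVA and by distance to the group's spatial median (vegan 2.7.1, 9999 permutations), with negative squared distances set to 0. Repeat samples were compared with 100000 random sets of 3 pairs from different participants. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the remaining steps.

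Tests, lists and the rule for named genes were fixed before the data were examined. The rule took protein-coding genes past the edgeR threshold with a mean of at least 10 CPM, the 12 with the smallest p in each direction. It added up to 4 members per list past the threshold with the smallest p, and 16 sperm, leukocyte and epithelial genes whatever their result. Genes of the Y chromosome and XIST were left out of the named genes. A few genes that the rule takes are not reported here.

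The statistics were tested on simulated data. With counts simulated for 31100 genes in infertility and proven-fertile participants, of which 200 were changed, edgeR recovered 28.4% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 98.5% of those changed 4-fold. It called 0.0194% of unchanged genes. With each library's GC trend simulated, 3.63% of unchanged genes were called, and 0.0162% with GC offsets. In the data far more genes were called (14591 of 31105), which puts the adjusted threshold at a larger p. These edgeR shares therefore do not carry over to the data. The rank-sum test on 2000 simulated genes recovered 52.5% of genes shifted by 1 SD and called 0.111% of unchanged genes.

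Alternatives fixed in advance were other normalisations, filters, tests and covariates, 2 surrogate variables (sva 3.50.0), DESeq2 1.42.0, gene length offsets in 20 bins, thinning to 1339489 counts, and the first library only of participants with 2. Added after the data were seen were offsets by GC content in 20 bins, the share of counts in genes under 40% GC (the low-GC share) as covariate, the 58 participants whose share lay in the range of both groups, comparisons with parts of the infertility group, and fold thresholds on the rank-sum result. The parts come from a step in the low-GC share along the order of the numbers in the infertility labels, placed where the means differed most with at least 5 participants on each side. They are not groups of the study, and no label gives a batch. The proven-fertile libraries could not be placed on either side of the step.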

Results

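Transcripts of spermatozoa were profiled in 53 participants under fertility assessment and 14 proven-fertile participants, to ask which transcripts differ in abundance between them. Total gene counts averaged 2035254 ± 311880 per library (SD, n = 56) in the infertility group and 2267097 ± 545943 (SD, n = 14) in the proven-fertile group. Between 36396 and 50235 of 57500 genes had a count in a library. Protein-coding genes took on average 74.7% of counts and the 100 most abundant genes 3.67%. Genomic DNA as a source of counts was not excluded (last paragraph), so the values below need not come from transcripts alone.

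Transcripts of PRM1, PRM2, TNP1 and TNP2, which encode proteins that package sperm chromatin, and of AKAP4 and ODF1, which encode proteins of the sperm tail, were lower in the infertility group. PRM1 and PRM2 encode the protamines, which replace histones in the condensing sperm nucleus. PRM1 (ENSG00000175646, chromosome 16, 11280836 to 11281350) stood at 504 ± 682 CPM (SD, n = 53) in the infertility group and 1733 ± 1358 CPM (SD, n = 14) in the proven-fertile group. This was a log2 fold change of -1.76 ± 0.49 (SE) with an edgeR adjusted p of 0.00228, and 48 of 53 infertility participants lay below the proven-fertile median. PRM2 (ENSG00000122304, chromosome 16, 11275639 to 11276480) stood at 216 ± 319.9 CPM (SD, n = 53) against 1136 ± 962 CPM (SD, n = 14), a log2 fold change of -2.38 ± 0.44 (SE, edgeR adjusted p = 1.63e-05), and 52 of 53 lay below the proven-fertile median. TNP1 and TNP2 encode transition proteins, which precede the protamines on DNA. TNP1 (chromosome 2, 216859458 to 216860064) changed by -1.69 ± 0.49 (log2, SE; edgeR adjusted p = 0.00373) and TNP2 (chromosome 16, 11267748 to 11269533) by -0.97 ± 0.22 (edgeR adjusted p = 0.000224). AKAP4, a main protein of the fibrous sheath (chromosome X, 50190768 to 50201013), changed by -1.59 ± 0.38 (edgeR adjusted p = 0.000444). ODF1, of the outer dense fibres (chromosome 8, 102551572 to 102561017), changed by -1.23 ± 0.29 (edgeR adjusted p = 0.000365). PRM1, PRM2, TNP1 and TNP2 each overlap a gene on the opposite strand. Over the alternatives, which include DESeq2, limma-voom and a rank-sum test beside edgeR fits, the adjusted p ranged from 4.44e-07 to 0.0565 for PRM1, 6.49e-10 to 0.00304 for PRM2, 1.49e-07 to 0.129 for TNP1, 2.17e-06 to 0.0224 for TNP2, 6.57e-11 to 0.155 for AKAP4 and 2.75e-08 to 0.0375 for ODF1.

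The infertility libraries fell into parts along their label numbers, 19 participants with a lower and 34 with a higher share of counts in genes under 40% GC, which was noticed in the data and is not a grouping of the study. Against the 19, the log2 fold changes of PRM1 (-1.08, edgeR adjusted p = 0.0565), TNP1 (-0.86, edgeR adjusted p = 0.129) and AKAP4 (-0.89, edgeR adjusted p = 0.0699) did not pass, whereas PRM2 (-1.68, edgeR adjusted p = 0.00304), TNP2 (-0.71, edgeR adjusted p = 0.0178) and ODF1 (-0.77, edgeR adjusted p = 0.0331) did. Against the 34, these genes passed, at -2.49 for PRM1, -3.15 for PRM2, -2.67 for TNP1, -1.23 for TNP2, -2.34 for AKAP4 and -1.67 for ODF1. The parts themselves differed in these genes, with PRM1 -1.53 ± 0.51 (log2, SE; edgeR adjusted p = 0.00782) and PRM2 -1.59 ± 0.46 (edgeR adjusted p = 0.00242) in the later relative to the earlier numbers.

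**Figure D1:**
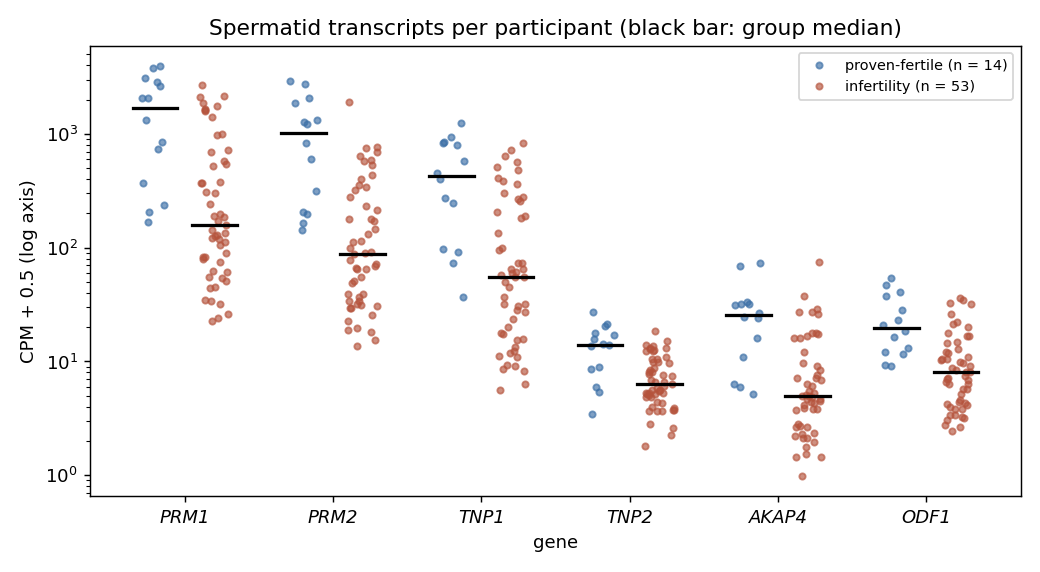
CPM (plus 0.5, log axis) of spermatid genes, with a point for each of 14 proven-fertile and 53 infertility participants and a black bar at each group median. The median of PRM1 is 157 CPM in the infertility group and 1684 CPM in the proven-fertile group, and both groups spread widely and overlap.

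Over the whole transcriptome, 14591 of 31105 tested genes passed the edgeR threshold, with 6412 higher and 8179 lower in the infertility group. Which direction had more calls depended on the setting, with 8811 higher and 7577 lower with 2 surrogate variables and 6335 higher and 5575 lower with limma-voom. By edgeR as first given, 882 were at least 2-fold higher and 1309 at least 2-fold lower. Across the tested genes the log2 fold change rose with gene GC content (Spearman rho = 0.352), and rho was -0.0847 with GC offsets. Among protein-coding genes, 3083 of 16763 were higher and 5321 lower, and among long intergenic RNAs 643 of 3370 were higher and 796 lower. Among protein-coding genes with a mean of at least 10 CPM, the smallest p values of lower genes belonged to the 12 genes that follow. CCDC188, a coiled-coil protein gene (chromosome 22, 20148427 to 20151065), stood at 6.54 ± 4.71 CPM (SD, n = 53) against 58.3 ± 92.3 CPM (SD, n = 14), a log2 fold change of -3.18 ± 0.29 (SE, edgeR adjusted p = 7.56e-13), and 53 of 53 infertility participants lay below the proven-fertile median. Its medians were 5.56 and 25 CPM, closer than the means, and with GC offsets its log2 fold change was -4.12. ANKRD9 (chromosome 14, 102501760 to 102509799) changed by -2.80 ± 0.27 and HPCA, encoding the neuronal calcium sensor hippocalcin (chromosome 1, 32885994 to 32898441), by -2.88 ± 0.29. Of these 12 genes, ANKRD9, HPCA, EHBP1, TJP1, PCF11, EFCAB13 and PPP6R3 overlap genes on the opposite strand. SRSF6, a splicing factor, changed by -1.43, RANBP2, of the nuclear pore, by -0.99, and PCF11, a factor of transcript 3' end processing, by -1.05. EHBP1 changed by -1.28, EFCAB13 by -1.27, ZNF302 by -1.13, PPP6R3 by -0.98, the endothelial cadherin CDH5 by -0.81 and the tight junction gene TJP1 by -0.66. With GC offsets ANKRD9 (-3.45), HPCA (-3.64) and CDH5 (-1.11) also changed more. The rest of these lower genes changed less, among them RANBP2 (-0.68), ZNF302 (-0.76) and EFCAB13 (-0.85).

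Among the higher genes of that set, PLCXD1 (chromosome X, 276322 to 303356) had the smallest p. It stood at 114 ± 26.4 CPM (SD, n = 53) against 48.5 ± 12.1 CPM (SD, n = 14), a log2 fold change of 1.20 ± 0.12 (SE, edgeR adjusted p = 1.41e-11), and 53 of 53 infertility participants lay above the proven-fertile median. EXPH5 (chromosome 11, 108505431 to 108593738) changed by 1.03 ± 0.11 and CHMP4A, of the ESCRT-III complex (chromosome 14, 24209583 to 24213869), by 1.20 ± 0.13. GATD1 changed by 1.25, the tetraspanin CD151 by 1.13, the RNA polymerase III subunit POLR3K by 1.04, ASMT by 0.94, GTF2IRD2B by 0.92, TRUB2 by 0.91, the scavenger receptor COLEC12 by 0.89, the lysosomal protein gene TMEM192 by 0.73 and the replication factor C subunit RFC2 by 0.72. With GC offsets EXPH5 (1.25), TMEM192 (0.81) and POLR3K (1.05) changed more. The rest of these higher genes changed less, among them GATD1 (0.81), CD151 (0.61) and RFC2 (0.47). PLCXD1 and ASMT lie in a region shared by the sex chromosomes and GTF2IRD2B has a near-identical paralog, so their counts are uncertain. COLEC12, TMEM192, POLR3K, TRUB2 and CD151 overlap genes on the opposite strand. Of these 24 genes, 24 were also called in the same direction by the rank-sum test and 24 against both parts of the infertility group. The genes were picked by their p over these same participants. Such agreement, also that of the called named genes below, is therefore no independent support. The largest edgeR adjusted p among them was 2.5e-09. Of the 111 called named genes, 103 were called in the same direction against both parts, the exceptions being LDHA, GPI, PKM, PTPRC, PRM1, TNP1, AKAP4 and CATSPER1, and 104 with GC offsets, the exceptions being GPI, RPL30, BAG6, LIG1, PTPRC, ELF3 and CATSPER1. Of the called named genes tested between the parts, 89 of 108 differed by edgeR. SYCP2 stood at -2.52 and -0.89 against the earlier and the later label numbers, DPY19L2 at -2.49 and -0.74, and KIT at -2.0 and -0.69. Against the earlier and later label numbers 16309 and 9486 genes were called by edgeR.

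**Figure D2:**
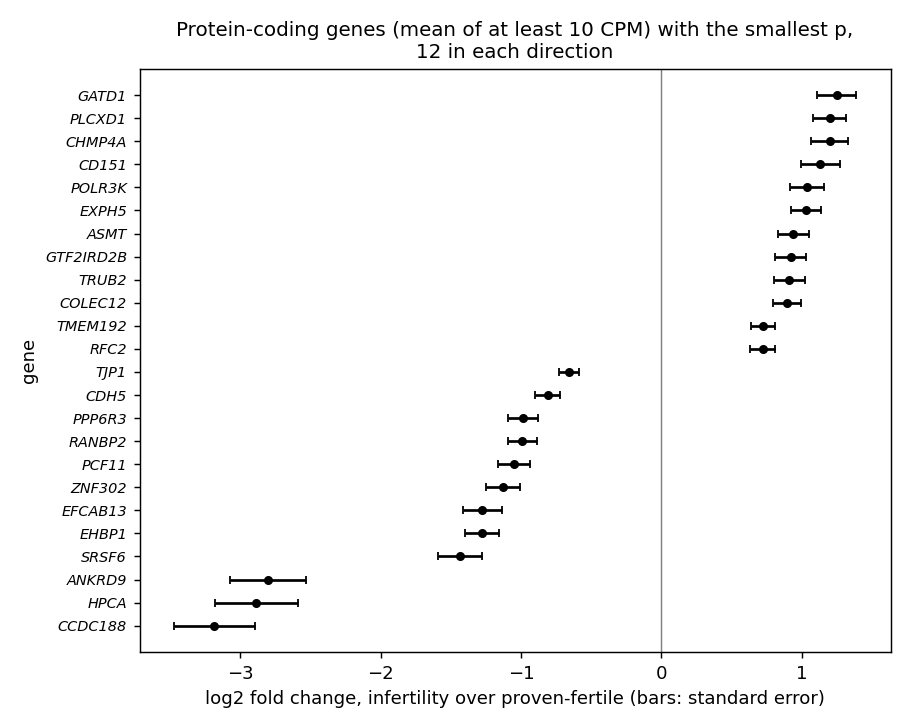
Log2 fold change (infertility over proven-fertile) with its standard error for the protein-coding genes with the smallest p among those with a mean of at least 10 CPM, 12 in each direction. The values run from -3.18 for CCDC188 to 1.25 for GATD1.

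On the deposited log2 values, the rank-sum permutation test called 11370 of 27809 genes, 5170 higher and 6200 lower. Of 27808 genes in both tests, 10840 were called by both in the same direction and 0 in opposite directions. It also called 109 of the 111 named genes that edgeR called, in the same direction. Both tests used counts of the same participants, so this overlap is no independent support. The series text deposited by the authors gives 1885 differentially abundant transcripts. The threshold behind that number is not given in the sources used here.

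Of the gene lists, spermatid transcription and translation control fell as a list, with 21 of 34 members lower and 3 higher (camera adjusted p = 0.0158). Its smallest p values belonged to TEX44 (log2 fold change -2.55), SPATA6 (-1.02), RFX3, a transcription factor of ciliated cells (-1.02), and MSI2, an RNA-binding protein (-0.56). The list did not pass against the earlier label numbers (camera adjusted p = 0.192) nor with 2 surrogate variables (camera adjusted p = 0.0594), and over the alternatives its adjusted p, from camera or fry, ranged from 1.62e-14 to 0.192.

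Sperm chromatin packaging had 12 of 17 members lower and 0 higher (camera adjusted p = 0.459), so it did not pass as a list with the estimated correlation. At an unadjusted p of 0.05 edgeR also found 0 higher members, and the rank-sum test called 11 lower and 0 higher. Its median log2 fold change was -1.25. SPEM1 changed by -1.92, ACTL7B by -1.79 and PRM3 by -2.19. With a preset correlation of 0.01 this list passed too (camera adjusted p = 0.00225), and of the 2 lists called that way only spermatid transcription and translation control held with an estimated correlation. Adjusted over the list alone, the counts of members were 9 lower and 3 higher for flagellum fibrous sheath and outer dense fibres, 16 lower and 9 higher for axoneme and dynein arms, 2 lower and 3 higher for sperm glycolysis, 22 lower and 7 higher for cytosolic ribosomal proteins, 11 lower and 7 higher for nuclear respiratory chain, 17 lower and 6 higher for chaperones, 12 lower and 10 higher for DNA repair, 8 lower and 9 higher for interferon response, 3 lower and 3 higher for leukocyte markers and 4 lower and 5 higher for Sertoli, Leydig and peritubular markers, and for the other lists as given here. The median, the mean and the direction of the camera test differed in sign for sperm ion channels and motility signalling (0.02, -0.08 and down), DNA repair (-0.09, -0.07 and up), epithelial, prostate and seminal vesicle markers (0.02, -0.01 and up) and Sertoli, Leydig and peritubular markers (0.03, -0.01 and up), in that order.

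Lists of the tail, acrosome and motility did not pass camera over all participants without a covariate. Fibrous sheath and outer dense fibres had 8 of 19 members lower and 3 higher (camera adjusted p = 0.662), among them AKAP3 at -1.57, FSIP2 at -1.07, TSGA10 at -0.84 and SPATA18 at -0.72. The axoneme had 16 of 44 members lower and 8 higher (camera adjusted p = 0.751), among them CFAP44 at -1.28, DNALI1 at -0.95, SPAG17 at -0.88 and CCDC39 at -0.78. The acrosome and egg binding list had 14 of 38 members lower and 4 higher (camera adjusted p = 0.478). With the low-GC share as covariate this list passed as lower (camera adjusted p = 0.0339), and over the alternatives its adjusted p, from camera or fry, ranged from 4.1e-05 to 0.960. Fry, which does not compare a list with other genes, called 10 lists, 8 lower and 2 higher. The lower ones were the fibrous sheath, axoneme, acrosome, chromatin packaging, spermatid transcription, meiosis, proteasome and chaperone lists. The higher ones were leukocyte markers and interferon response. The fusion gene LLCFC1 was at -2.03, IZUMO3 at -1.19, DPY19L2, needed for acrosome attachment, at -1.17 and ADAM20 at -1.05. PLCZ1, the egg-activating phospholipase, changed by -0.87 (edgeR adjusted p = 0.000124). IZUMO1 (-0.52, edgeR adjusted p = 0.0581) and the acrosin gene ACR (-0.61, edgeR adjusted p = 0.0788) did not pass, though both did with GC offsets (-0.71 and -0.81). IZUMO1 was at -0.09 (edgeR adjusted p = 0.795) against the earlier and -0.92 (edgeR adjusted p = 0.000583) against the later label numbers, and the parts differed by -0.95 (edgeR adjusted p = 3.05e-06). Ion channels and motility signalling had 12 of 32 members lower and 8 higher (camera adjusted p = 0.992). SLC9C1, a sperm sodium-proton exchanger, was at -0.98 and the potassium channel KCNU1 at -0.54, whereas CATSPERD was at 0.88 and CATSPER2 at 0.65. CATSPER1 passed at 0.43 (edgeR adjusted p = 0.0377) but not with GC offsets (0.22, edgeR adjusted p = 0.0943), nor against either part, and over the same alternatives of several tests its adjusted p ranged from 1.66e-05 to 0.770.

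Sperm glycolysis had 4 of 18 members lower and 3 higher (camera adjusted p = 0.751), among them HK3 at 1.38, GPI at 0.44, LDHA at 0.27 and PKM at -0.27. The call of GPI was lost with GC offsets (0.22) and against the later label numbers (0.20). LDHA (0.16) and PKM (-0.19) lost theirs against the earlier label numbers. LDHC did not pass (0.32, edgeR adjusted p = 0.0823), though it did with GC offsets (0.60), and GAPDHS, at 2.18 ± 2.10 CPM (SD, n = 53) and 2.58 ± 1.51 CPM (SD, n = 14), was too low to be tested. Meiosis and the piRNA pathway had 19 of 36 members lower and 6 higher (camera adjusted p = 0.514), among them SYCP2 at -1.30, MAEL at -0.81, SYCE2 at 1.11 and MSH5 at 0.73. CRISP2, a gene of the sperm acrosome and tail, was at 0.20 ± 0.48 (log2, SE) over all participants and did not pass (edgeR adjusted p = 0.748). It was at 1.14 against the earlier label numbers (edgeR adjusted p = 0.0332) and at -1.0 against the later ones (edgeR adjusted p = 0.0407), and over the same alternatives of several tests its adjusted p ranged from 0.00353 to 0.944. Between the parts it differed by -2.24 (edgeR adjusted p = 7.36e-07).

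Housekeeping lists did not pass camera either. Ribosomal proteins had 24 of 76 members lower and 7 higher (camera adjusted p = 0.751), among them RPL41 at -0.65, RPS25 at -0.53, RPL23 at -0.43 and RPL30 at 0.39. Mitochondrially encoded proteins had 0 of 13 members lower and 0 higher (camera adjusted p = 0.751), with 0 lower at an unadjusted p of 0.05 in edgeR and 1 lower by the rank-sum test. The nuclear respiratory chain had 12 of 48 members lower and 7 higher (camera adjusted p = 0.751), among them NDUFA13 at -1.16, NDUFV2 at -0.88, COX7B2 at 0.88 and COX6B2 at 0.69. The proteasome and ubiquitin list had 17 of 44 members lower and 5 higher (camera adjusted p = 0.342), among them PSMB1 at -0.75, PSMA1 at -0.66, PSMB7 at -0.54 and PSMD11 at -0.47. Chaperones had 16 of 33 members lower and 6 higher (camera adjusted p = 0.478), among them DNAJB8 at -1.82, HSPH1 at -1.05, BAG5 at -0.63 and BAG6 at 0.52. BAG6 was at 0.02 with GC offsets, where it did not pass. HSPA2, a testis chaperone, did not pass (-0.23, edgeR adjusted p = 0.133). It was at -0.72 (edgeR adjusted p = 0.000364) against the earlier and -0.04 (edgeR adjusted p = 0.839) against the later label numbers, and the parts differed by 0.54 (edgeR adjusted p = 1.63e-06). Antioxidant enzymes had 8 of 27 members lower and 4 higher (camera adjusted p = 0.751). GPX4, the selenoenzyme of the sperm midpiece, was at -1.19, NME8 at -1.01, TXNDC2 at -0.99 and PRDX3 at 0.65. DNA repair had 11 of 39 members lower and 10 higher (camera adjusted p = 0.992), among them NBN at -1.0, LIG1 at 0.71, ERCC1 at 0.67 and XRCC2 at 0.59. The interferon response had 7 of 27 members lower and 8 higher (camera adjusted p = 0.751), among them IFITM2 at 1.37, IRF9 at 1.02, HERC5 at -0.70 and ISG20 at -0.64. Fry called the interferon list higher (fry adjusted p = 0.0130). RPL30 and LIG1 did not pass with GC offsets (0.14 and 0.27), and the call of ISG20 was lost under an alternative fixed in advance.

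Markers of other cell types went both ways. Leukocyte markers had 4 of 24 members lower and 3 higher (camera adjusted p = 0.751), among them CD74 at 0.79, ITGAX at 0.72 and CD3E at -0.54. Fry, which does not compare a list with other genes, called this list higher (fry adjusted p = 0.0117). The call of CD3E was lost under an alternative fixed in advance. PTPRC, which encodes the leukocyte common antigen, changed by -0.66 (edgeR adjusted p = 0.00983), a call lost with GC offsets (-0.31). Epithelial, prostate and seminal vesicle markers had 2 of 20 members lower and 4 higher (camera adjusted p = 0.751), among them KRT5 at -0.83, CLDN4 at 0.67 and ELF3 at 0.57. ELF3 did not pass with GC offsets (0.19). KRT18 did not pass (0.07, edgeR adjusted p = 0.831). Chosen after their values were seen as the most abundant markers, ITGB2 of leukocytes stood at 136 ± 30.7 against 104 ± 61.5 CPM (SD) and KRT8 of epithelia at 186 ± 38.6 against 115 ± 63.1 CPM (SD). Epididymal markers had 5 of 19 members lower and 3 higher (camera adjusted p = 0.879), among them LCN8 at 0.87, SLC34A2 at 0.57, ADAM28 at -0.75 and DEFB118 at -0.66. Sertoli, Leydig and peritubular markers had 5 of 25 members lower and 5 higher (camera adjusted p = 0.751), among them INSL3 at 0.95, CYP11A1 at 0.91 and COL1A2 at -0.56. Spermatogonia and early germ cell markers had 8 of 21 members lower and 2 higher (camera adjusted p = 0.751), among them KIT at -1.03, PIWIL4 at -0.89, CCND2 at -0.74 and DMRT1 at 0.71.

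**Figure D3:**
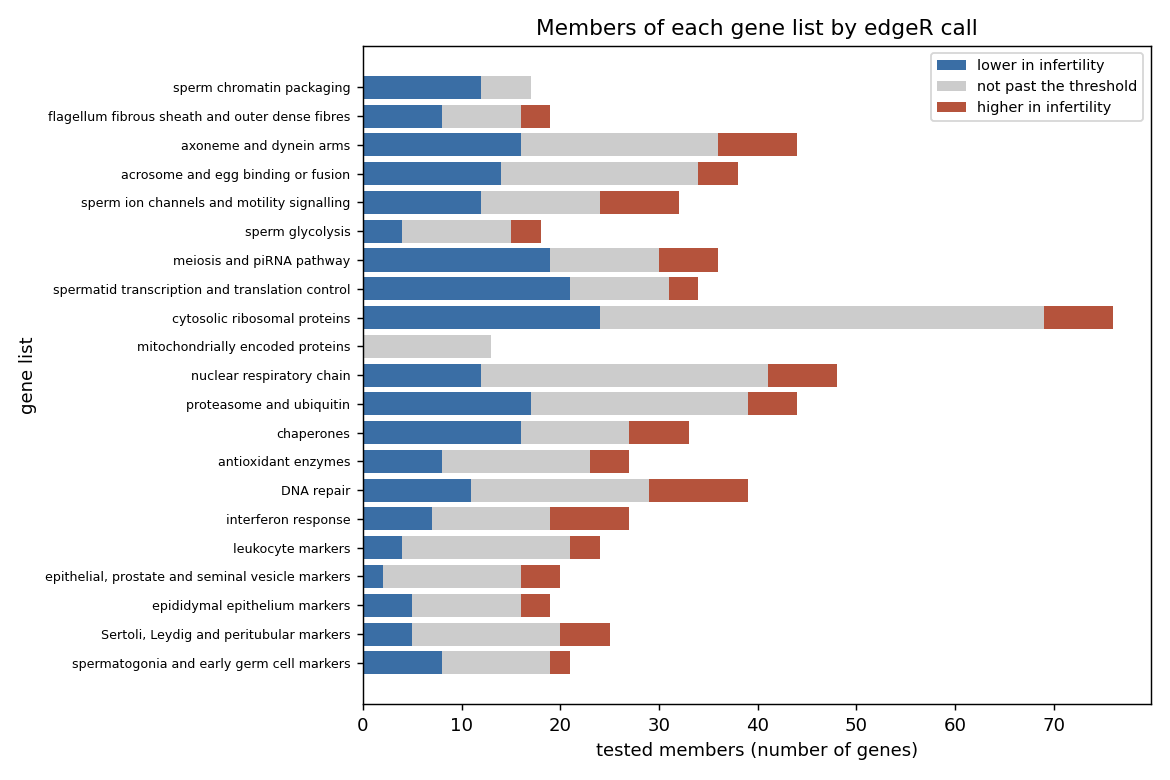
Number of tested members of each of 21 gene lists that were lower, not past the edgeR threshold or higher in the infertility group. Sperm chromatin packaging has 12 lower and 0 higher members, and spermatid transcription and translation control 21 lower and 3 higher.

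The composition of the libraries differed between groups. The 100 most abundant genes took 3.60% ± 0.473 (SD, n = 53) of counts in the infertility group and 4.06% ± 0.377 (SD, n = 14) in the proven-fertile group (two-sided permutation test, p = 0.00119, adjusted p = 0.00476 over 4 properties). The means differed by -0.459 percentage points. By medians, an alternative fixed in advance, the difference was -0.526 and did not pass (permutation test, adjusted p = 0.0683). The earlier label numbers stood at 3.96% ± 0.468 (SD, n = 19) and did not pass (permutation test, adjusted p = 0.720), and the later ones at 3.40% ± 0.338 (SD, n = 34) (permutation test, adjusted p = 4e-05). Log10 total counts (adjusted p = 0.467), genes detected (adjusted p = 0.299) and the mitochondrial share (adjusted p = 0.436) did not pass the same permutation test. The share of counts in genes under 40% GC, examined after the data were seen, was 11.4% ± 2.42 (SD, n = 53) against 14.9% ± 4.67 (SD, n = 14) (permutation p = 0.000360). It was 8.80% ± 1.14 (SD, n = 19) in the earlier and 12.9% ± 1.54 (SD, n = 34) in the later label numbers (permutation test of the largest step, p = 1e-05, the smallest the resamples can give). Against the proven-fertile group the permutation p of this share was 1e-05 for the earlier and 0.0264 for the later label numbers. The first principal component of log2 CPM followed the share, with Pearson r = 0.976 and Spearman rho = 0.976 in the infertility group and r = 0.961 and rho = 0.974 in the proven-fertile group (each permutation p = 1e-05, adjusted 1.75e-05 over 14 relations). Without the 2 participants of each group farthest from the median share, r was 0.971 and 0.970. It was 0.947 within the earlier and 0.955 within the later label numbers.

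**Figure D4:**
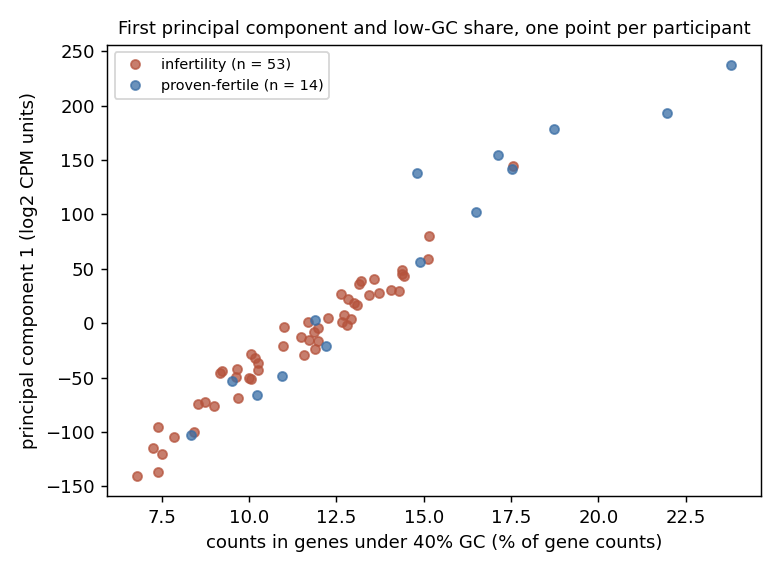
First principal component of log2 CPM against the percent of gene counts in genes under 40% GC, with a point per participant. The component, with 31% of the variance, follows this share in both groups, and the proven-fertile group covers a wider range.

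The group accounted for 16.1% of the variation between whole profiles (PERMANOVA permutation p = 0.0003). Against the earlier label numbers this was 42% (permutation p = 0.0001, the smallest the permutations can give), and against the later ones 5.80%, which did not pass (permutation p = 0.0913). Profiles of the infertility group lay closer to their centre, at a mean distance of 0.0876 ± 0.0441 (SD, n = 53) against 0.152 ± 0.0907 (SD, n = 14) in the proven-fertile group (permutation p = 0.0005). The difference was -0.0779 against the earlier and -0.0916 against the later label numbers (permutation p = 0.001 and 0.0001). Over all participants it was -0.0646, and -0.0379 with GC offsets (permutation p = 0.0047). A difference in spread also enters the PERMANOVA.

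Repeat samples of a participant were closely alike, with a mean Spearman correlation across genes of 0.951 ± 0.00259 (SD, 3 pairs) against 0.875 ± 0.0557 (SD) over 1537 pairs of libraries from different infertility participants (one-sided permutation p = 1e-05, the smallest the resamples can give). The ranges overlapped, with the lowest repeat pair at 0.948 and the highest pair from different participants at 0.950. Over genes with a mean of at least 10 CPM, pairs from different participants reached 0.950, above the highest repeat pair (0.943). The 834 pairs of different participants from the same side of the step, earlier or later, averaged 0.906 ± 0.0380 (SD). All 3 participants with repeat samples lay after the step. Against sets of pairs drawn from that side alone, the permutation p was also 1e-05. Each of the 6 repeat libraries was most like its partner.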

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

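Settings that involve GC content, parts of the infertility group or a fold threshold were chosen after the data were seen. The number of genes called by edgeR ranged from 10134 to 18533 over the alternatives within 1.5 times of 14591, and was 9486 against the later label numbers. The comparison with the earlier label numbers, with 19 infertility participants rather than 34, called 16309. The earlier part also lay farther from the proven-fertile group (PERMANOVA 42% against 5.80% for the later part). Whether fewer participants lowered the count to 9486 therefore cannot be told from these counts. The share of calls that were higher, 43.9%, was 29.8% with GC and length offsets together (4229 higher and 9969 lower). It was 53.8% with 2 surrogate variables (8811 higher and 7577 lower), and more genes were also higher with limma-voom (6335 higher and 5575 lower), detected genes (9104 higher and 8216 lower), total counts (8004 higher and 7899 lower) or the low-GC share (5624 higher and 5421 lower) as covariate. Scaling by total count alone gave 6985 higher and 6993 lower, and limma on the deposited log2 values 7546 higher and 7121 lower, where the rank-sum test gave 5170 higher and 6200 lower. The median log2 fold change of all tested genes was -0.07, and over the alternatives it ranged from -0.15 with GC and length offsets to 0.03 with 2 surrogate variables. The rank-sum test called 6614 genes among those above the median level, where fewer were tested. After the count of 1885 in the series text was known, 2 thresholds with a 2-fold difference of mean log2 values were tried, which gave 1897 genes at an adjusted p of 0.05 and 1656 at 0.01. The closeness of the first to the authors' count is the outcome of that search and does not show which threshold they used. Camera called 1 list. A preset correlation called 2, fry, which does not compare a list with other genes, 10, the low-GC share as covariate 2, the acrosome list being the one gained, 2 surrogate variables 0 (4 at an unadjusted p of 0.05) and the earlier label numbers 0 (1 unadjusted). Of library properties 1 passed, and 0 by medians (1 unadjusted) and 0 against the earlier label numbers (0 unadjusted), all by permutation tests. PERMANOVA gave 5.80% and no call against the later ones. The cause was not tested for the list, property and PERMANOVA changes. The other PERMANOVA, spread and repeat sample alternatives kept direction and call, though with GC offsets the spread difference was -0.0379, where it was -0.0646 without.

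Of 111 called named genes, 106 kept direction and call in each alternative fixed in advance and 81 in the added ones too. Calls were lost under an alternative fixed in advance for CATSPER1, CD3E, ISG20, PKM and PTPRC, and only under added ones for genes that included ADAM28, AKAP4, BAG6, CCDC39, COL1A2, COX6B2, CYP11A1, DEFB118, DPY19L2, ELF3, GPI, HERC5, ITGAX, KCNU1, LDHA, LIG1, PLCZ1, PRM1, RPL23, RPL30, RPL41, RPS25, SPATA6 and TNP1. Over all named genes and alternatives, 2771 of 2909 values kept direction and call, 82 lost the call, 33 gained one, 19 changed sign with no call either way and 4 changed sign with a call on one or both sides. The sign changed for BAG6 (-0.0201 with GC and length offsets), PTPRC (0.105) and DEFB118 (0.0722) with the low-GC share as covariate, and CRISP2 (-1.0) against the later label numbers. The cause was not tested. Leaving out participants under 1000000 counts gave no value, since there were none. No paired analysis was possible because the groups hold different participants with unrelated label numbers. In the simulation 28.4% of 1.5-fold changes were recovered, a share that does not carry over to the data. Recovery in the data is not known, so an uncalled gene is not shown to be unchanged.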

Other observations

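The tests on GC content, library size, label order, other cell types and genomic DNA, the correlations, the check of the first sperm RNA test against the step and the second version of that test were chosen only after the result was seen. Spermatid transcripts moved together between participants. PRM1 followed TNP1 in the infertility group (Pearson r = 0.981, Spearman rho = 0.980) and in the proven-fertile group (r = 0.984, rho = 0.987). Each permutation p was 1e-05, the smallest the resamples can give, and 1.75e-05 after Benjamini-Hochberg adjustment over 14 relations. Without the participants farthest from the median of PRM1, 2 in each group, r was 0.978 and 0.978, and within the infertility group it was 0.984 before and 0.972 after the step in label order. The relation with TNP2 in the infertility group was looser (r = 0.482, permutation p = 0.000280, adjusted 0.000392; rho = 0.492, permutation p = 0.000230, adjusted 0.000358). It was 0.425 without the 2 farthest, 0.502 before the step, and 0.285 after it, which did not pass (permutation p = 0.104). In the proven-fertile group PRM1 and TNP2 did not pass either (r = 0.396, permutation p = 0.161, adjusted 0.174, and rho = 0.530, permutation p = 0.0539, adjusted 0.0580), with r = 0.714 without the 2 farthest. Of the 30 genes that followed PRM1 most closely in the infertility group, 28 had a log2 fold change below 0, among them LELP1 (-2.63), HMGB4 (-1.50) and TMCO2 (-1.34), chosen after their values were seen. The 30 were picked from these same data by following PRM1, itself lower, so this is no independent support. Of all 477 genes that followed PRM1 there (Spearman of at least 0.6), 142 were called lower and 124 higher, with a median log2 fold change of 0.06. In 27 of 53 infertility participants PRM1 lay below the lowest proven-fertile value.

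Of the tested genes, 46.9% passed the edgeR threshold between groups, and chance assignment of participants can be excluded, since 1 of 100 splits called as many genes, the real one with 14591 and the highest other with 11 and likewise 1 for the rank-sum test by normal approximation (11253 against 1). For the lists 3 of 100 splits called as many as the real 1, under the threshold for chance, and the highest other called 4. GC content and library size as the whole cause are argued against by the 13706 genes called with GC offsets and the 12687 called after thinning. Library batches stay open, and batch and group cannot be told apart, because no label places the proven-fertile libraries. The infertility participants before and after the step differed in 17819 genes, more than the groups did at other group sizes. With GC offsets they differed in 16201. The step was placed by the low-GC share of these same counts, so a high count was likely in advance and decides nothing. Over all participants and, with GC offsets, against both parts, 6344 of 28125 genes were called in the same direction. These comparisons share the proven-fertile participants, so a batch of those libraries could give the same calls. The number therefore does not separate batch from group.

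The lower PRM1, PRM2, TNP1, TNP2, AKAP4 and ODF1 may reflect fewer late spermatid transcripts in the infertility group. The labels name only the group, and this reading was not tested apart from batch. GC content is argued against by their median log2 fold change of -1.64 with GC offsets and -1.64 without, under a bound that was loosened after a stricter one (no change toward 0) was narrowly missed. Leukocytes or epithelial cells, which the lysis step would remove, stay open, since the highest median log2 fold change of their marker lists, 0.13, lies over members called both ways, and the abundant markers ITGB2 at 136 ± 30.7 against 104 ± 61.5 CPM (SD) and KRT8 at 186 ± 38.6 against 115 ± 63.1 CPM (SD) had higher means in the infertility group. Fry also called the leukocyte list higher (fry adjusted p = 0.0117), though camera did not. A smaller share of sperm RNA stays open: a prediction made in advance came out against it, with 46.8% of 477 genes that followed PRM1 in the infertility group at a log2 fold change below 0, but 454 of these genes were themselves lower after than before the step, so the set cannot be told apart from the step. After that result the test was run again on 49 genes that followed PRM1 on both sides of the step, of which 85.7% had one below 0 (median -1.49), between its bounds.

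Reads fell on most annotated genes in each library (36396 to 50235 of 57500). In every participant, 45.4% of all genes and 78.4% of protein-coding genes were counted. Genomic DNA that covers genes evenly is a candidate source. Over 3259 protein-coding genes with at least 8000 bp of exons, reads per kb at the 90th percentile were 6.67 times those at the 10th. This lay between the bounds for an even and an uneven cover, which were set after the data were seen. The ratio therefore decides nothing, and genomic DNA as a source stays open. No biological explanation was tested for this pattern.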
